A study of Mus musculus with 4 samples.

How the data were processed

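Total RNA was measured on 4 expression arrays of mouse cells, per the labels. The groups are amplified dendritic cell progenitors grown from bone marrow, cells after 7 days of differentiation in culture, cells after 10 days, and cells after 10 days that also received tumour necrosis factor (TNF) for 16 hours. There is 1 array in each group. No replicate spread exists, so no test and no p-value is given, and genes are not used as replicates. The labels do not say how many cultures or mice stand behind each array.

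The deposited values are probe-set intensities on a linear scale, 1 per probe set and array, for 12654 probe sets of an Affymetrix mouse array. The software, background method, scaling and detection calls behind these intensities are not given in the sources used here; the labels cite a published protocol for RNA preparation, labelling and hybridisation. The deposited values themselves show that 22.8% to 24.3% of probe sets on each array lie below 0, so a background or mismatch value had been subtracted. They also show that the mean of the central 96% of probe sets is between 998.8 and 999.03 on every array, so the authors had already matched the arrays in brightness. The tables hold no scan date or batch label.

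Probe sets were named through the platform annotation. Of the 12654 probe sets, 10298 have 1 gene symbol, 363 have several and 1993 have none. Symbols were updated through the Entrez gene number for 10279 probe sets. Probe sets with several symbols or none were left out of gene counts, as were 66 control probe sets. For each gene the probe set with the highest mean over the 4 arrays was used, which left 8220 genes, 1609 of them with more than 1 probe set. No genome coordinates are printed, because the build behind the annotation is not given in the sources used here.

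From the deposited intensities, each array was scaled to a common 75th percentile, the geometric mean over the 4 arrays, by factors of 0.962 to 1.05. Values were then raised to a floor at the 40th percentile of all scaled values, 105 units, and converted to log2. A gene was counted as higher or lower when 2 arrays differed at least 2-fold. These counts and the medians of gene lists use the floor of 105 units. Because values near 105 units lie within the noise of the arrays, the total counts are also given with a stricter floor at the 60th percentile, 428 units, and so are results of the lists that this floor alters most. Folds of single genes use the stricter floor: where the dimmer array lies under 428 units the fold is written as a lower bound against 428 units ("at least"), and where both lie under it no fold is given. Levels are scaled intensities, and negative levels are printed as they stand. Log2 ratios of other probe sets of a gene use the floor of 105 units. Where both arrays lie at or under that floor such a ratio is 0.00 and is no measure of change.

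Gene lists were fixed before the data were examined: 21 lists of pathways and cell programmes and 10 lists of markers of cell types that the cultures could hold, together 870 genes, of which 691 were measured. The lists cover haematopoietic progenitors, granulocytes and primary granules, the cell cycle, DNA replication, MHC class II and class I presentation, dendritic cell identity and maturation, the NF-kB and TNF response, chemokines, transcription regulators, pattern recognition and Fc receptors, interferon response, lysosome, ribosome biogenesis, ribosomal proteins, cholesterol synthesis, glycolysis, oxidative phosphorylation, actin and adhesion, and housekeeping. The marker lists cover macrophages, mast cells and basophils, eosinophils, erythroid cells, megakaryocytes, B cells, T and NK cells, plasmacytoid dendritic cells, stromal cells, and genes restricted to other organs as a measure of background. A list's median log2 ratio was taken over members above 105 units on at least 1 of the 2 arrays. Its place among the medians of 10000 random lists of the same size, matched on mean level in 20 bins, describes these arrays and is no test.

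The genes named were chosen by a rule fixed at the same time. For each of 3 comparisons it takes the 6 highest and the 6 lowest log2 ratios among genes above 105 units on both arrays. It adds the 3 brightest higher and the 3 brightest lower genes whose other side is at that floor, and in each list described up to 4 members with the largest ratio. Another 22 genes were named in advance for every comparison, and all 22 were measured. Day 10 against progenitor is given by counts, lists and those 22 genes. Any gene outside the rule is said to have been chosen after its values were seen.

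The error estimate used for log2 ratios is the disagreement between the 2 brightest probe sets of a gene, both above 105 units on both arrays. Its SD on the log2 scale was 0.83 for day 7 against progenitor over 672 genes, 0.85 for day 10 against day 7 over 665, 1.08 for day 10 against progenitor over 635, and 0.74 for TNF against day 10 over 674. It covers the behaviour of probes in 1 pair of hybridisations, not cultures or repeat arrays, and the number of arrays limits the precision of every value.

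The procedure was tested on simulated data for the comparison of day 7 with progenitor, over 8220 genes. It recovered 95.0% of genes made 4-fold different and 94.0% of those made 8-fold different, and it counted 297 of 8020 unchanged genes as different at the floor of 105 units and 105 at the stricter floor. The simulated noise had an SD of 124 units and of 0.31 on the log2 scale. No spread between cultures or repeat arrays was known, so these numbers are not error rates of the counts below. The alternatives tried were the values as deposited, quantile normalization, floors at the 25th and 60th percentiles, the mean of all probe sets of a gene, leaving out probe sets whose name marks possible cross-hybridisation, and a 3-fold size rule. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.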

Results

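The study followed dendritic cells, the antigen-presenting cells that start T cell responses, as they differentiated in culture from amplified bone marrow progenitors. Gene expression was measured in the progenitors, after 7 days, after 10 days, and after 10 days with TNF, a cytokine that matures dendritic cells, for 16 hours. There was 1 array per group, with no replicate, so every difference below is one between 2 arrays. On each array 22.8% to 24.3% of the 12654 probe sets had a value below 0, and 3888 to 3991 of the 8220 genes lay above 428 units. Among 41 measured genes restricted to other organs, such as albumin, the median level was 35.0 units on the progenitor array, 23.8 at day 7, 68.9 at day 10 and 34.3 with TNF, and 5 to 9 of them lay above 428 units. Across probe sets, which are not independent replicates, Spearman's rho between arrays lay between 0.822 for progenitor and TNF and 0.910 for day 10 and TNF.

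The first comparison, of day 7 with the progenitor, asks which transcripts separate differentiating cells from the progenitors. MHC class II genes, whose products present peptides to CD4 T cells, stood far higher at day 7. H2-Aa was at -492 units on the progenitor array and 20686 at day 7, at least 48.3-fold higher, and H2-Eb1, H2-DMa and H2-Ab1 were at least 34.6-fold, 28.7-fold and 28.0-fold higher. The invariant chain gene Cd74 was 8.43-fold higher, at 20060 units, a log2 ratio of 3.08 that became 3.93 after quantile normalization. Of 15 class II list members above 105 units, 13 were at least 2-fold higher and 0 lower, and the list median of 3.05 lay above the medians of all 10000 random lists. The dendritic cell integrin Itgax, which encodes CD11c, was at least 14.5-fold higher at 6188 units.

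Genes linked to maturation were higher at day 7 as well, in cells that had received no TNF per the labels. Of 29 members of the maturation list above 105 units, 18 were higher and 1 lower, with a median of 1.54, above all random lists; at the floor of 428 units 13 were higher and 0 lower. The chemokine genes Ccl5 and Ccl17 were at least 16.7-fold and 14.1-fold higher, Ccr7, the receptor that guides dendritic cells to lymph nodes, at least 10.0-fold at 4296 units, and Cd83 at least 7.19-fold. Cd86, a T cell costimulatory gene, was at least 2.60-fold higher, while Cd80 and Cd40 lay under 428 units on both arrays. In the list of chemokines and their receptors 11 of 25 members were higher and 2 lower, with Ccl4 at least 6.41-fold higher. In the NF-kB and TNF response list 15 of 32 were higher and 1 lower (8 and 1 at the floor of 428 units), among them Icam1, at least 5.0-fold higher, Nfkb2, at least 3.88-fold, and Tnf itself, at least 1.88-fold. The inhibitor gene Nfkbia was 1.72-fold lower, and Saa3, the 1 member counted as lower, was 8.25-fold lower.

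Transcription regulators of dendritic cell development formed a list of which 18 of 46 members were higher and 3 lower, with a median of 0.64. Irf8 was 6.43-fold higher at 3774 units, Irf4 at least 4.45-fold higher, and Relb at least 3.19-fold, although a second Relb probe set gave a log2 ratio of 0.71. Klf4 and Egr2 were at least 10.4-fold and 5.13-fold higher, and Atf3 at least 11.6-fold by a probe set shared within a gene family, with log2 ratios of 2.57 and 0.00 from its 2 other probe sets. Id2, an inhibitor of helix-loop-helix factors, was at 7731 and 13138 units (1.70-fold), and Spi1, which encodes PU.1, at 8219 and 12494 (1.52-fold); both were bright in progenitors already. Id3 stayed under 428 units. In the dendritic cell identity list 8 of 17 members were higher and 3 lower, with Ly75 and Anpep at least 6.14-fold and 5.58-fold higher. Ccr2 differed by only 1.05-fold.

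Macrophage markers were higher as well. Of 17 members of that list, 10 were higher and 4 lower, with a median of 1.94, or 1.12 at the floor of 428 units. The elastase gene Mmp12 was at least 41.3-fold higher at 17697 units, the mannose receptor gene Mrc1 at least 16.4-fold, Lpl 17.1-fold and Csf1r 7.38-fold. A second probe set of Csf1r did not follow, with a log2 ratio of -1.27. That of Lpl lay at or under 105 units on both arrays, so its ratio of 0.00 is no measure of change. The complement gene C1qc was at least 3.92-fold lower. Of 32 lysosome genes, 15 were higher and 0 lower, with Lipa 7.75-fold, Ctss 5.13-fold (log2 ratio 2.36, or 3.48 after quantile normalization) and Lgmn at least 7.70-fold higher. Among pattern recognition and Fc receptors 8 of 24 were higher and 2 lower, with Fcgrt 5.36-fold higher, and in the interferon response list 11 of 25 were higher and 0 lower (5 and 0 at the floor of 428 units), with Lgals3bp 4.31-fold and Gbp2 at least 2.73-fold higher. Plet1, which encodes a membrane protein, and Fstl1, which encodes a secreted one, were at least 26.6-fold and 14.1-fold higher.

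Proliferation genes were lower at day 7. Of 29 cell cycle genes 22 were lower and 0 higher (median -1.42), and of 28 DNA replication genes 18 were lower and 0 higher (median -1.48); both medians lay below those of all random lists. Top2a, which untangles chromosomes, was 3.54-fold lower, Ccne1 4.45-fold, Foxm1 4.15-fold, Aurkb at least 5.84-fold, and the replication licensing genes Cdc6 and Mcm5 were 4.81-fold and 3.90-fold lower. Ribosome biogenesis genes followed, with 11 of 26 lower and 0 higher (median -0.84), among them Gnl3, 4.01-fold, and Nop56, 3.46-fold.

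Some granulocyte genes were lower too, among them 3 whose products fill the primary granules of early granulocyte precursors. Ctsg was 11.8-fold lower, Prtn3 7.47-fold (log2 ratio -2.90, or -3.56 after quantile normalization), Mpo 4.95-fold (-2.31, or -2.92), at 26660 and 5381 units, and the granulocyte regulator Gfi1 10.2-fold. Over the whole granulocyte list only 6 of 18 members were lower and 2 higher (median -0.23), inside the range of random lists. Its brightest members lay close to the top of these arrays, where the highest probe set was at 41044 units in progenitors and 30560 at day 7. Chil3 (29597 and 29255 units) and S100a8 (27286 and 23848), both chosen after their values were seen, are examples. The highest probe set was at 137313 units at day 10 and 89121 with TNF, so a flat ratio of such members may hide a difference. Mmp9, a gelatinase gene of later granules, was at least 3.16-fold higher. Myb, a progenitor regulator, was 8.11-fold lower, and Flt3 2.45-fold, with a second Flt3 probe set at a log2 ratio of -0.23. Kit had the opposite sign, 2.02-fold higher at 1308 units, and Cd34 lay under 428 units on both arrays. In the haematopoietic progenitor list 5 of 14 were lower and 3 higher, or 2 and 3 at the floor of 428 units. Among genes above 105 units on both arrays the lowest ratio belonged to fibronectin, Fn1, at 14592 and 390 units and at least 34.1-fold lower. Ces2g, Orm1, Psmd1 and P4hb were at least 17.1-fold, 7.93-fold, 6.60-fold and 6.10-fold lower. Cstf1, at least 4.14-fold lower, and Mtm1, 9.77-fold lower, also ranked among the lowest, but second probe sets of both gave ratios of the opposite sign, 1.69 and 1.03 on the log2 scale.

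In all, 796 genes were at least 2-fold higher and 709 at least 2-fold lower at day 7, of 5957 above 105 units on at least 1 array. With the stricter floor the counts were 453 and 419, and with a 3-fold rule 390 and 264.

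**Figure D1:**
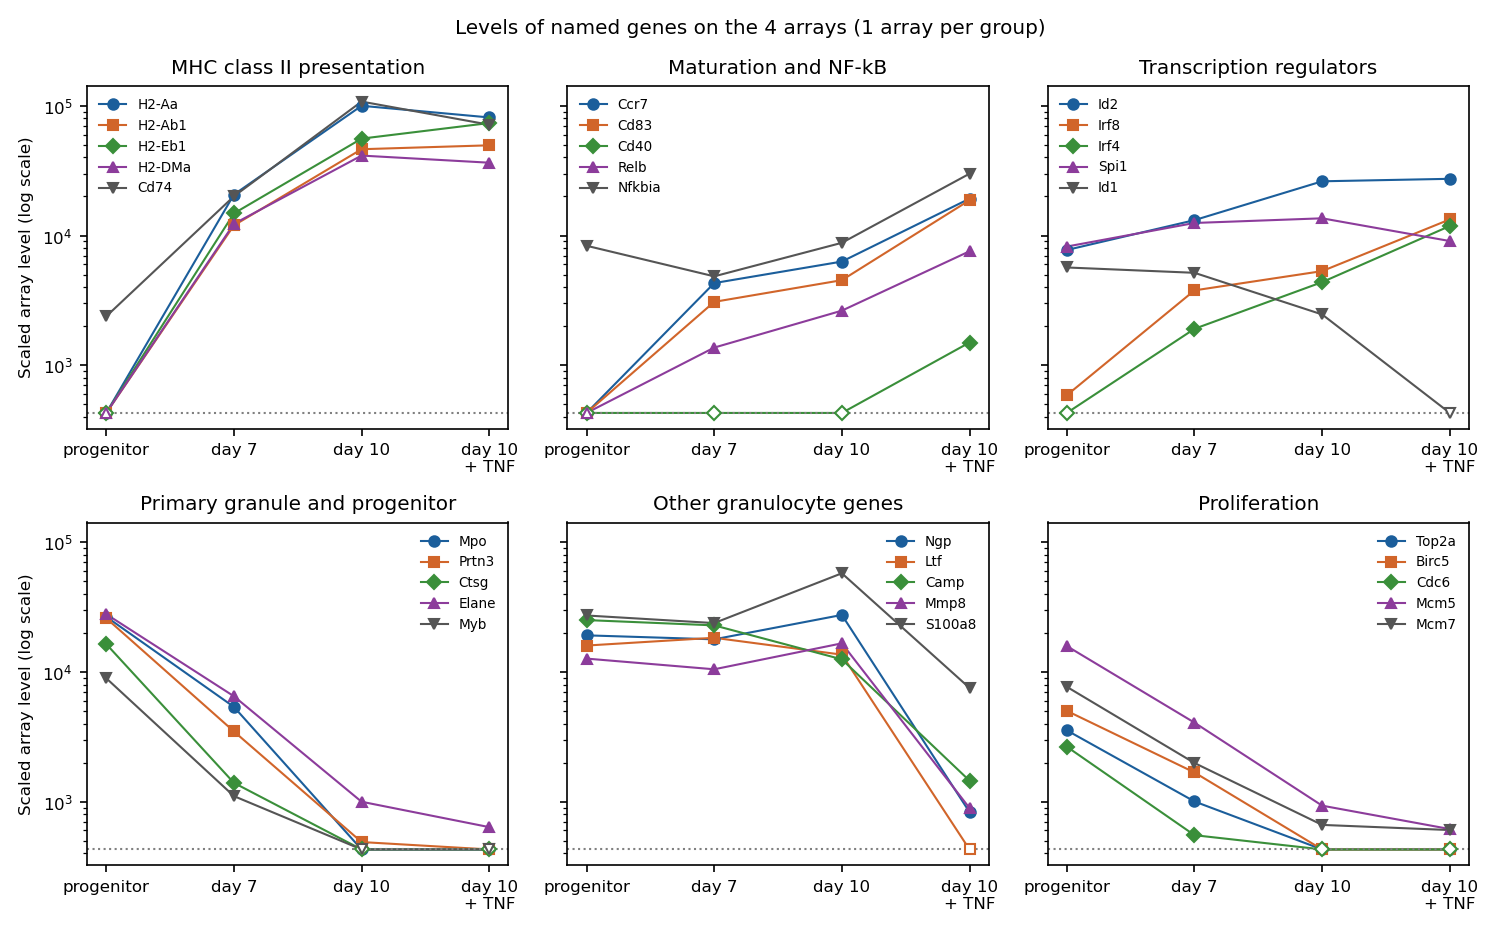
Scaled level of named genes on the 4 arrays, on a log axis, in 6 panels by group; each marker is 1 array, and open markers lie under 428 units (dotted line) and are drawn there. H2-Aa stood at 20686, 100111 and 81388 units at day 7, day 10 and day 10 with TNF, and Ngp at 27554 at day 10 and 831 with TNF. Camp and S100a8 lie outside the naming rule and count as chosen after their values were seen. Chil3, a granulocyte list member with a log2 ratio of only -0.44 with TNF, is not drawn.

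The second comparison, of day 10 with day 7, asks how the last days of differentiation differ from the first. These 2 arrays also differed in controls that are not made by the cells, given below, so day and array cannot be fully separated. Proliferation genes were lower still. Of 28 cell cycle genes 19 were lower and 0 higher (median -1.98), and of 28 DNA replication genes 18 were lower and 0 higher (median -1.55), both below all random lists. Quantile normalization gave -2.01 and -1.59, while at the floor of 428 units the medians were -0.98 with 12 lower and -1.0 with 11 lower. Birc5, which encodes survivin, was at least 3.92-fold lower, Top2a at least 2.34-fold, Ckap2 at least 2.05-fold, and Pclaf, a PCNA-binding factor, at least 5.77-fold. The 2 other Pclaf probe sets gave -1.37 and 0.00, the latter the value that the floor of 105 units gives. On the day 10 array Top2a, Cdc6, Cdc45 and Nek2 had levels of -28, 46, 39 and 37 units, all under 105.

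Among granulocyte genes the lowest ratios belonged to 4 primary granule genes. Mpo was at least 12.6-fold lower at 200 units, Prtn3 7.13-fold, Elane 6.51-fold and Ctsg at least 3.26-fold, and 8 of 18 granulocyte list members were lower and 2 higher, with a median of -0.65, below all random lists, or -0.43 at the floor of 428 units; after quantile normalization 10 were lower and 0 higher (-1.26). A second, dimmer Mpo probe set gave a log2 ratio of 0.68. Cst7, which encodes a cystatin, was at least 2.46-fold lower. Cholesterol synthesis genes were lower, 7 of 16 against 1 higher (median -0.83, below all random lists), but only 3 were lower and 0 higher at the floor of 428 units (median -0.28), with Fdft1, the squalene synthase gene, 3.65-fold lower. Tnf was at least 1.88-fold lower, and Myb at least 2.58-fold.

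On the higher side, glycolysis genes stood out, with the same limit that day and array cannot be fully separated. Of 17 members 10 were higher and 1 lower, with a median of 1.26 (0.93 after quantile normalization), above all random lists under both. The glucose transporter gene Slc2a1 was 5.07-fold higher and Aldoa 3.59-fold, with a second Aldoa probe set at a log2 ratio of 0.95. Pgk1 and Tpi1 were 3.90-fold and 3.32-fold higher (log2 ratios 1.96 and 1.73, or 1.45 and 1.21 after quantile normalization), and both had been lower at day 7 than in progenitors. The maturation list had 6 of 28 members higher and 0 lower. Its median of 0.61 lay at the 99.94th percentile of random lists but under the 0.76 of genes restricted to other organs. Within it Ccl17 was 6.23-fold higher at 37488 units (log2 ratios 2.64 and 2.10), the interleukin-7 receptor gene Il7r 5.19-fold and Socs3 2.66-fold, while Cd83 and Ccr7 were each 1.47-fold higher, Cd86 was 1.07-fold lower, Cd80 lay near 428 units and Cd40 under it. Irf4 was 2.29-fold higher, Relb 1.93-fold, Ccr2 1.88-fold, Nfkbia 1.81-fold, Irf8 1.41-fold and Csf1r 1.56-fold. Second probe sets of Relb and Nfkbia had the opposite sign, at -0.50 and -0.86. Flt3 was 1.56-fold lower, with a second probe set at 1.22, Kit differed by 1.04-fold, and Id3 and Cd34 lay under 428 units. The integrin gene Itgam, a myeloid marker, was 3.04-fold lower.

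Many of the brightest transcripts were brighter on both day 10 arrays, and so were control probe sets that do not come from the cells. The 9 probe sets for bacterial transcripts spiked into the samples had a median log2 ratio of 1.5 between day 10 and day 7 (2.83-fold), with a range of 1.2 to 1.77. Their median was -0.34 between day 7 and progenitor and -0.50 between TNF and day 10. Probe sets at a mean level of 2^14 to 2^15 had a median log2 ratio of 1.0 between day 10 and day 7, those above that 1.63, and those at 2^11 to 2^12 0.03. For genes above 2^14 units at day 10, ratios to day 7 are therefore given also after quantile normalization. It gives all arrays the same distribution, so it shrinks a true rise shared by bright genes as well as one from the arrays. The values after it are an alternative, not a correction. Mid-level ratios hardly change under it, as for Aldoa (1.85 and 1.87).

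MHC class II genes were among these bright transcripts. Cd74 was 5.38-fold higher, a log2 ratio of 2.43 that became 0.77 after quantile normalization, and H2-Aa 4.84-fold, 2.27 that became 0.54. H2-Ab1 and H2-Eb1 kept log2 ratios of 1.25 and 0.96 after quantile normalization, against 1.95 and 1.92. Over the list 11 of 15 members were higher, or 6 of 15 after quantile normalization, with 0 lower in either, and the median of 1.73, or 0.89, lay above all random lists under both. Those lists were matched in wide bins at the bright end, so this place is less certain for a list with such bright members. Itgax was 3.41-fold higher (log2 ratios 1.77 and 1.37) and Id2 1.99-fold (1.0 and 0.35). Spi1 differed by 1.09-fold, with a log2 ratio of 0.12 that turned to -0.25. The lysosome list had 9 of 33 members higher, or 4 after quantile normalization, and 0 lower, with medians of 0.70 and 0.20; Ctsd kept 1.76 of its 2.56, and Ctss had 1.83 and -0.06. In the MHC class I list 4 of 15, or 2, were higher and 0 lower (0.74 and 0.21), where B2m kept 1.09 of 1.95, and H2-D1 had 1.62 and -0.07. Macrophage markers had 5 of 14, or 3, higher and 1 lower (0.73 and 0.21), with Mmp12 at 1.79 and 0.57. Ribosomal protein genes had 16 of 19 higher and 0 lower, with a median of 1.59, or 0.30 with 5 higher and 1 lower after quantile normalization.

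The genes with the largest ratios at day 10 came mostly from families of near-identical genes. Actb was 26.5-fold higher than its day 7 level of 469 units, which was itself 6.63-fold under the 3111 units in progenitors. Actg2 was 22.8-fold higher (log2 ratios 4.51 and 4.15), Rpl41 17.6-fold (4.14 and 3.26), and the kallikreins Klk1b22 and Klk1b1 at least 6.25-fold and 5.66-fold. All 5 were read by probe sets whose names mark them as shared within a gene family. The 3 beta-actin control probe sets were higher too, at 11256 to 14295 units at day 7 and 88983 to 101211 at day 10. Serf2 was 25.2-fold higher, and Hgfac and H2-M1 at least 5.04-fold and 4.63-fold. Ifna9, an interferon gene with near-identical relatives, was at least 3.17-fold lower, and entries named as pseudogenes, Snrp1c-ps2 and Tmem250-ps, were at least 4.94-fold higher and 3.11-fold lower.

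In all, 686 genes were at least 2-fold higher and 517 lower at day 10 than at day 7, of 6123 above 105 units on at least 1 array. The stricter floor gave 314 and 201, a 3-fold rule 288 and 195, and quantile normalization 578 and 585, so that the share of higher genes was 57.0% in the main scaling, 49.7% after quantile normalization and 47.5% in the values as deposited. Genes restricted to other organs had a median of 0.76 with 5 of 18 higher and 2 lower, at the 99.99th percentile of random lists, so a shift of this size also occurred among genes read as background. The medians of the maturation (0.61), lysosome (0.70), macrophage (0.73) and MHC class I (0.74) lists were no larger. However, the other-organ genes were mostly dim, with medians of 23.8 units at day 7 and 68.9 at day 10, so they do not match brighter lists in level. Among level-matched random lists those 4 lists lay at the 99.94th, 99.8th, 99.2th and 99.9th percentile. After quantile normalization they lay at the 99.97th, 98.1th, 92.1th and 93.6th.

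**Figure D2:**
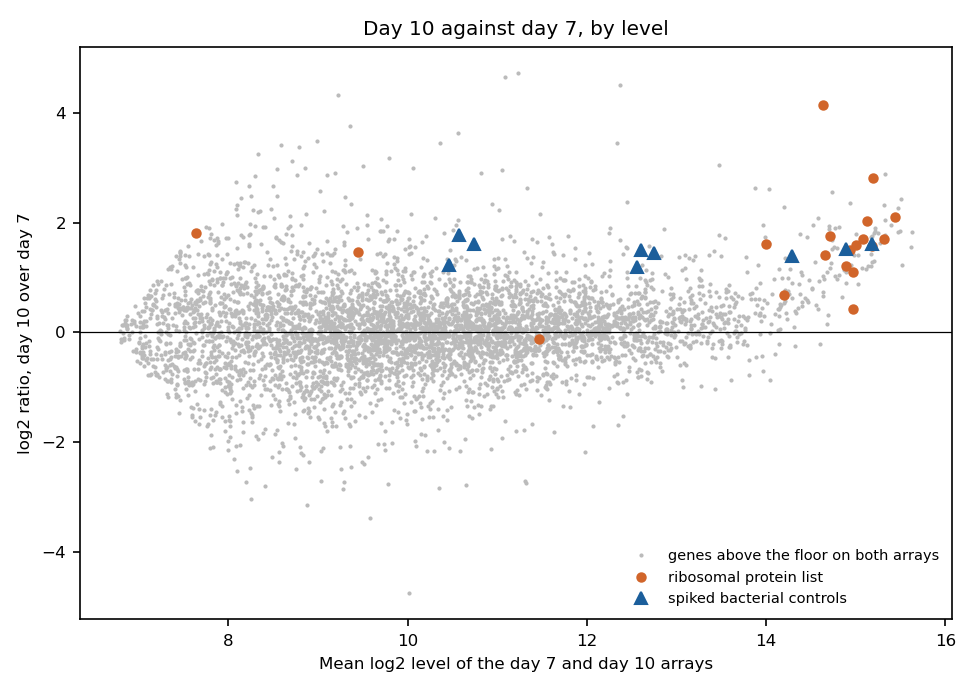
Log2 ratio of day 10 over day 7 against the mean log2 level of both arrays; grey points are genes above 105 units on both arrays, orange points the ribosomal protein list and blue triangles the 9 spiked bacterial controls. The controls lay between 1.2 and 1.77, and genes bent upward above a log2 level of 14.

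Set directly against the progenitor, the day 10 array differed by more genes than either step, with 1264 at least 2-fold higher and 1043 lower of 6198. The stricter floor gave 771 and 660, a 3-fold rule 711 and 494, and quantile normalization 1108 and 1169. All 15 class II list members above 105 units were higher (median 4.48), with H2-Aa at least 234-fold higher, Cd74 45.3-fold and Itgax at least 49.2-fold. Maturation genes had 23 of 30 higher and 1 lower (1.99), with Ccr7 and Cd83 at least 14.7-fold and 10.6-fold higher and Cd86 at least 2.43-fold; Cd80 was at 471 units and Cd40 at 146. Second probe sets of Relb, at least 6.15-fold higher, and Csf1r, 11.6-fold, did not follow, with log2 ratios of 0.20 and 0.37. Irf4 was at least 10.2-fold higher, Irf8 9.06-fold, Id2 3.39-fold, Kit 2.10-fold, Ccr2 1.79-fold and Spi1 1.65-fold. The macrophage list had 10 of 17 higher and 5 lower (2.86) and the lysosome list 21 of 34 higher and 0 lower (1.75).

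Against these, 25 of 30 cell cycle genes were lower and 0 higher (-3.35), as were 25 of 28 DNA replication genes (-3.05), 9 of 15 cholesterol synthesis genes against 1 higher (-1.24) and 13 of 26 ribosome biogenesis genes (-1.0). At the floor of 428 units the DNA replication median was -1.83. Mpo was at least 62.3-fold lower and Flt3 was 3.81-fold lower, but a second Mpo probe set gave a log2 ratio of only -1.66 and a second Flt3 probe set 1.0. Nfkbia differed by 1.05-fold, with log2 ratios of 0.08 and, after quantile normalization, -0.19. A second Nfkbia probe set was lower in both steps, at -0.54 for day 7 against progenitor and -0.86 for day 10 against day 7. Tnf, Id3 and Cd34 lay under 428 units on both arrays. The array differences in bright transcripts and in spiked controls apply here too. The controls had a median log2 ratio of 1.18. After quantile normalization the log2 ratio of Cd74 was 4.70 in place of 5.50 and that of Id2 1.25 in place of 1.76. Ribosomal protein genes had 14 of 19 higher in the main scaling (1.23) and 4 higher with 1 lower after quantile normalization (0.04). Glycolysis genes, which were higher at day 10 than at day 7, had 6 of 19 higher and 0 lower than in progenitors (0.53). After quantile normalization 5 were higher and 1 lower (-0.11), and both medians lay inside the range of random lists.

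The last comparison asks how day 10 cells given TNF differ from those without it. Genes of maturation were higher with TNF: 20 of 29 list members were higher and 0 lower, with a median of 1.21, above all random lists. Cd40, the receptor through which T cells license dendritic cells, was at 146 and 1496 units, at least 3.49-fold higher. Cd83 was 4.14-fold higher at 18714 units, Traf1 4.16-fold, Tnfsf4 3.82-fold, Ccr7 3.06-fold at 19239 units, and the costimulatory genes Cd80 and Cd86 2.79-fold and 2.32-fold, with second probe sets at 0.48 and 3.04. The actin bundling gene Fscn1 was 3.13-fold higher and Marcksl1 3.08-fold.

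The NF-kB and TNF response list had 17 of 37 members higher and 2 lower (median 0.80, above all random lists). Nfkbia, the inhibitor that NF-kB itself induces, was 3.41-fold higher at 29967 units, Icam1 5.12-fold, Relb 2.87-fold, Il1b at least 5.03-fold and Bcl3 at least 2.03-fold. Junb was 8.25-fold higher, with a second probe set at 0.71. Tnf lay under 428 units on both arrays. Among genes above 105 units on both arrays the highest ratio belonged to Cfb, complement factor B, at 167 and 7795 units and at least 18.2-fold higher. Inhba, the activin A gene, was 7.31-fold higher, Acod1, which makes itaconate, at least 4.35-fold, the C-type lectin gene Clec4e at least 4.20-fold, and Ccnd2 and Vldlr at least 5.20-fold and 4.14-fold. Second probe sets of Acod1 and Vldlr gave 0.48 and 0.00. Of the chemokines and their receptors 7 of 29 were higher and 4 lower (-0.01, or 0.49 at the floor of 428 units), with Ccl9 3.95-fold and Ccl22 2.91-fold higher.

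Among regulators 10 of 50 were higher and 6 lower (-0.04). Irf4 and Irf8 were 2.71-fold and 2.5-fold higher, while Id2 was level at 27368 units (1.05-fold) and Spi1 was 1.5-fold lower. Id1 was at 2461 and -25 units, at least 5.75-fold lower, and Notch1 was at least 2.07-fold lower. In the dendritic cell identity list 5 of 19 were higher and 0 lower, with Ly75 4.41-fold higher. Itgax was 1.38-fold higher, Csf1r 1.07-fold, and Flt3 and Kit each 1.19-fold, while Ccr2 was 1.74-fold lower. Id3, Cd34 and Mpo lay under 428 units on both arrays.

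Class II genes differed little. H2-Aa was 1.23-fold lower (log2 ratio -0.30, or 0.10 after quantile normalization) and Cd74 1.51-fold lower, 2 of 15 list members were higher and 0 lower, and the median was 0.10. The 2 were Ifi30, a lysosomal thiol reductase gene, 2.47-fold higher, and H2-Ob, at least 1.65-fold. The class I list had a median of 0.36 (99.8th percentile) with 1 of 14 higher, Cd1d1, 3.26-fold, and Psmb8 and Tap1 were 1.95-fold and 1.73-fold higher. Interferon response genes had a median of 0.43 (99.9th percentile), with 3 of 26 higher and 2 lower. The 3 were Gbp2, 3.65-fold higher, and Mx1 and Usp18, at least 3.01-fold and 2.79-fold.

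Granulocyte genes were far lower with TNF. Of 18 members 11 were lower and 0 higher, and the median of -1.65 lay below all random lists. Ngp was at 27554 and 831 units, 33.2-fold lower, Ltf was at least 31.8-fold lower, Mmp8 18.6-fold, Pglyrp1 at least 7.50-fold and Mmp9 at least 3.24-fold. Chil3, chosen after its values were seen, was the exception among bright members, at 85765 and 63141 units. Ifitm6 and the cytokine gene Il18 were at least 14.3-fold and 7.82-fold lower, and Itgb5 and Tspan4 at least 7.20-fold and 4.05-fold. Eosinophil markers were lower too: 3 of 4 were lower and 0 higher (median -1.21, below all random lists), with the granule genes Prg2 and Epx 2.67-fold and 2.35-fold lower, although a second Prg2 probe set gave 0.75. Lysosome genes were slightly lower as a list (median -0.54, or -0.39 after quantile normalization, below all random lists under both), with 1 of 34 lower, Lipa at 2.10-fold, and 1 higher. The spiked controls had a median of -0.50 between the same arrays. Macrophage markers had 4 of 16 lower and 0 higher (-0.32, just inside the range of random lists), with Mrc1 3.32-fold and Adgre1 2.5-fold lower. Pattern recognition receptors had 3 of 24 lower and 1 higher (-0.40), with Scarb1 2.42-fold lower.

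With TNF 544 genes were at least 2-fold higher and 539 lower, of 6151 above 105 units on at least 1 array. The stricter floor gave 203 and 222 and a 3-fold rule 177 and 177.

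**Figure D3:**
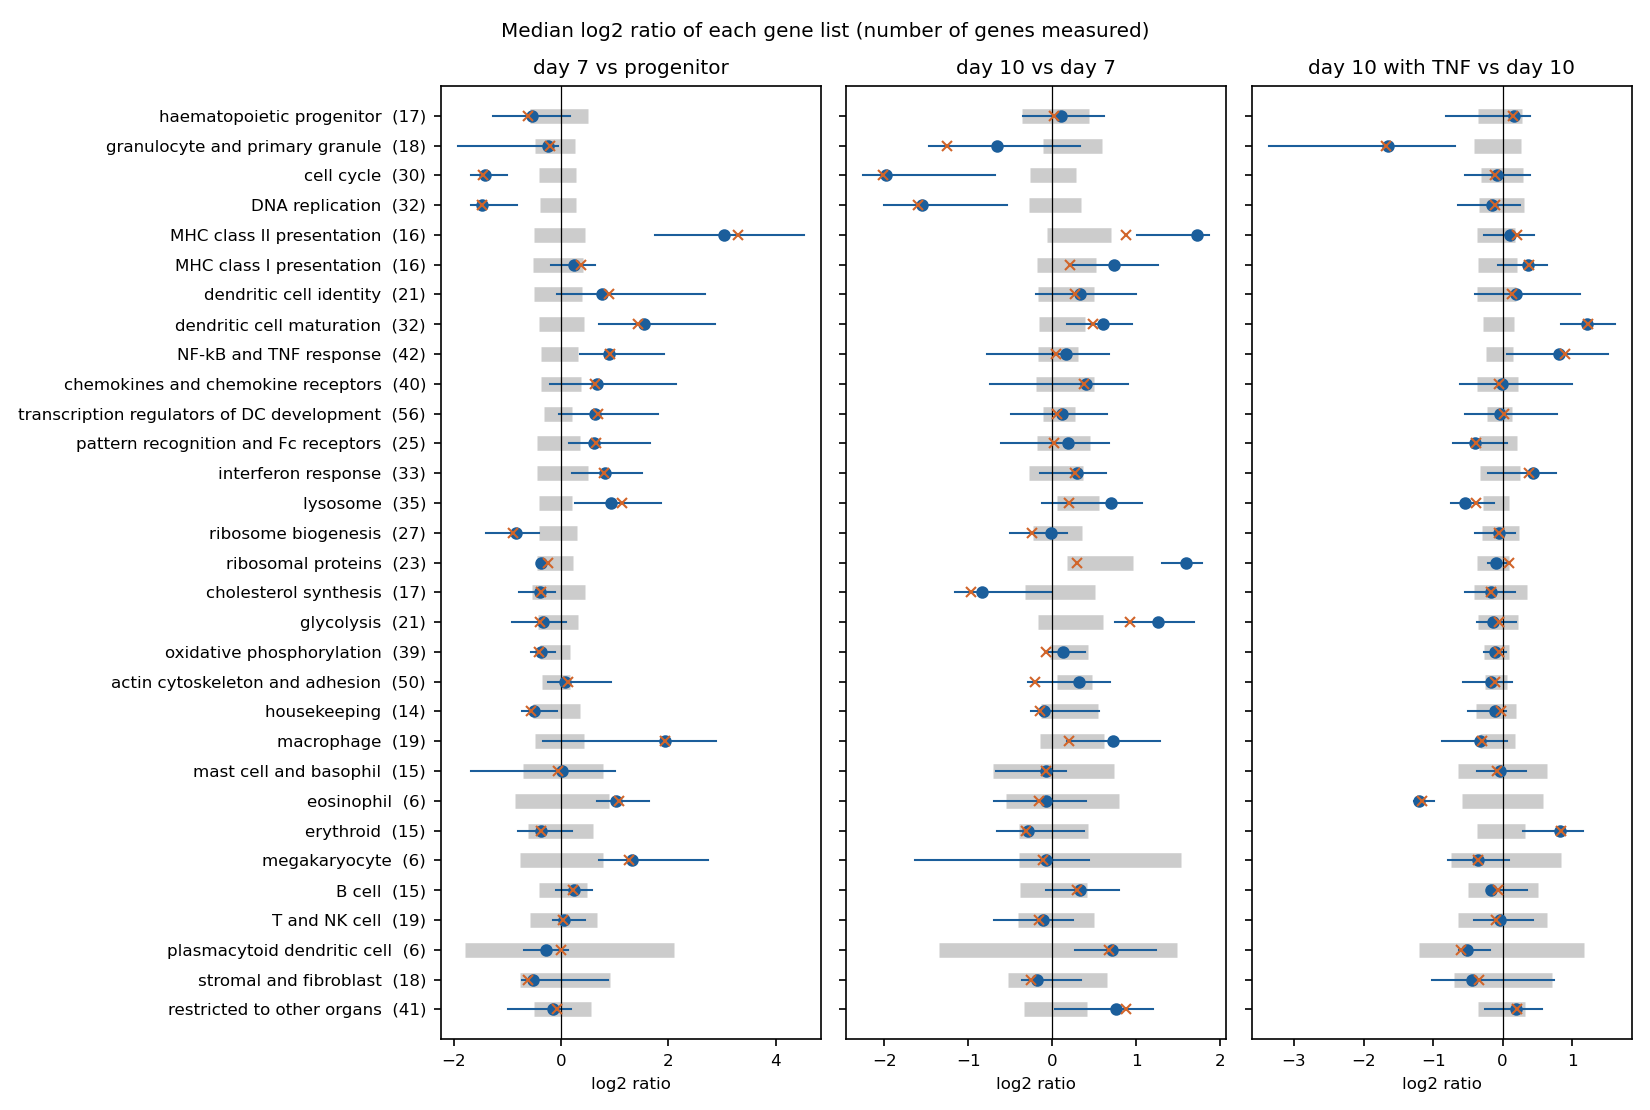
Median log2 ratio (blue point) of each gene list in 3 comparisons, with the interquartile range of its members (blue line), the central 95% of 10000 level-matched random lists (grey bar) and the median after quantile normalization (orange cross). MHC class II stood at 3.05 at day 7 and at 0.10 with TNF, where maturation stood at 1.21 and granulocyte genes at -1.65.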

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

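Of the tests in this part, those on bright probe sets, on spiked controls, on the brightness of the TNF array and on granulocyte content were chosen after the result was seen; the percentile of ribosomal protein genes was fixed beforehand. Control probe sets that enter no comparison carried a signal on some arrays. The 3 prime probe set for 18S ribosomal RNA was at 260 units on the progenitor array and 204 at day 7, but at 5637 at day 10 and 5058 with TNF. The 5 prime probe set was below 0 on the first 2 arrays and at 1001 and 4450 units on the others, while the middle one was at 76 units at day 10 and -1464 with TNF. The 9 spiked bacterial controls had a median log2 ratio of 1.5 between day 10 and day 7. The control probe set for Fas, a death receptor of the TNF receptor family, was at 218 units in progenitors, 655 at day 7, 551 at day 10 and 2899 with TNF.

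The first pattern is that abundant transcripts were higher on both day 10 arrays. Bright probe sets outside the ribosomal and MHC lists had a median log2 ratio 1.2 above that of mid-level ones. That value restates the pattern for other genes, so it cannot decide on a cause. The highest level of any probe set was 41044 units on the progenitor array and 30560 at day 7, against 137313 at day 10 and 89121 with TNF. A compressed bright range on the earlier arrays may therefore account for much of the pattern. The spiked controls, which are not made by the cells, had 1.5, so a difference in hybridisation between the 2 pairs of arrays may also contribute. Yet a dim control (BioB-M, at 825 units at day 7 and 2807 at day 10) rose like a bright one (CreX-3, at 21303 and 64769). Probe sets other than controls at a mean level of 2^10 to 2^11 had a median of only 0.003. Up to the level of CreX-3 the controls therefore do not show a compressed bright range, which leaves brighter levels open. A shift like theirs does not by itself give a shift confined to bright transcripts. The ribosomal protein list lay at the 99.1th percentile of random lists or higher under both scalings, which met the prediction for a true excess; but random lists were matched in wide bins at the bright end, and against the 20 nearest genes in level, a check added after the result was seen, the median excess was 0.28 on the log2 scale with 13 of 19 genes above their neighbours, or 0.46 with 15 of 19 after quantile normalization. Whether ribosomal protein transcripts differed between day 10 and day 7 cells therefore cannot be told apart from the arrays' response, because each day lies in its own pair of arrays.

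The second pattern is that granulocyte genes were lower with TNF. A dimmer bright range on the TNF array is argued against, since the list median lay 1.24 below (-1.24) the lower bound of level-matched random lists. Fewer granulocytes in the TNF culture predicted that all 9 list members above 3000 units at day 10 would be at least 2-fold lower. It also predicted an SD of their log2 ratios no larger than the 0.74 between probe sets of a gene. Neither part was met, since 8 of the 9 were at least 2-fold lower and the SD was 1.51. Chil3, which macrophages also express, was at -0.44. Most of these members were lower all the same, so the test does not decide. Fewer granulocytes and lower expression within cells cannot be told apart here, because no cell counts or sorted fractions were used and 1 array stands on each side.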

How the results depend on the processing

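With 1 array per group no replicate was left out, and the floor sets how many genes are counted. No paired analysis was possible because each group has 1 array. Signal over background limits every dim gene: the floor of 105 units lies inside the array noise, whose SD was estimated at 124 units. All of the alternatives were fixed in advance.

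Of the values for gene lists 649 moved by less than their error, 94 moved further and 1 turned sign; for named genes the numbers were 2239, 351 and 10, and for counts and other summaries 92, 28 and 0 in the last place. Values as deposited moved none of them beyond that. A turned sign was counted only for lists whose main median lay outside the central 95% of random lists and for genes at least 2-fold different.

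Lowering the floor to the 25th percentile (7.89 units) gave 1343 higher and 1292 lower genes at day 7 against progenitor, 1271 and 1125 at day 10 against day 7, 1698 lower at day 10 against progenitor, and 1169 and 1156 with TNF, and raised the disagreement between probe sets to an SD of 1.33 for day 10 against day 7 and 1.23 with TNF. Raising it to 428 units gave 453 and 419, 314 and 201, 771 and 660, and 203 and 222, in the same order of comparisons, since fewer genes lie above it. The 3-fold rule gave 390 and 264, 288 and 195, 711 and 494, and 177 and 177. At day 7 against progenitor 3 lists had a median below the central 95% of random lists, against 5 under quantile normalization, 5 with the lower floor and 5 with the mean of probe sets; the cause was not tested.

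By that rule signs turned in these cases, and the cause was not tested. Without probe sets marked for cross-hybridisation, which leaves another probe set of the gene, the log2 ratio became -0.16 for H2-M3, 1.03 for Mtm1 and 2.87 for Spib (day 7 against progenitor), 0.31 for Bgn and 0.68 for Mpo (day 10 against day 7) and -0.67 for Bgn with TNF. The mean of probe sets gave 0.88 for Spib at day 7 and 0.41 for Atp5d at day 10 against day 7. Quantile normalization gave -0.063 for Ctss and -0.072 for H2-D1 at day 10 against day 7. The dendritic cell identity list had a median of -0.040 with TNF at the floor of 428 units, against 0.20.

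Smaller values also turned sign under quantile normalization and are not in those numbers, for example Spi1 at day 10 against day 7 (-0.25), Nfkbia at day 10 against progenitor (-0.19), H2-Aa with TNF (0.10), and the lists of actin and adhesion (0.33 to -0.20) and oxidative phosphorylation (0.13 to -0.07) at day 10 against day 7, glycolysis at day 10 against progenitor (0.53 to -0.11) and ribosomal proteins with TNF (-0.10 to 0.09).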

Other observations

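Some transcripts of other lineages differed between the arrays. With TNF the erythroid marker list had 3 of 11 members higher and 1 lower and a median of 0.83, above all random lists: Car2, a carbonic anhydrase gene, was 6.16-fold higher at 13531 units, Hbb-bh1, an embryonic globin gene, 3.74-fold, and Cpox, of haem synthesis, 2.56-fold, while Nfe2 was at least 2.26-fold lower. A second Hbb-bh1 probe set gave a log2 ratio of -1.0. At day 7 the eosinophil genes Epx and Prg2 were higher than in progenitors, Epx at least 7.33-fold and Prg2 2.29-fold, 2 of 4 list members with 0 lower; a second Prg2 probe set gave a log2 ratio of only 0.38. Vwf, an endothelial and platelet gene, was at least 16.5-fold higher at day 7 and stood at 13758 units at day 10. Its second probe set lay at or under 105 units at day 7 and in progenitors, so its ratio of 0.00 is no measure of change. Of 3 megakaryocyte genes above 105 units 2 were higher and 0 lower. The mast cell genes Cpa3 and Hdc were at least 3.83-fold and 2.07-fold lower at day 7, with 3 of 9 list members higher and 4 lower. Stromal markers had 2 of 8 higher and 1 lower, the latter Fn1. T and NK cell markers (2 of 8 higher, 1 lower), B cell markers (1 of 11 higher, 1 lower) and plasmacytoid dendritic cell markers (0 of 2 higher, 1 lower) differed in few members at day 7. The last was Spib, whose second probe set had the opposite sign, at a log2 ratio of 2.87. The plasmacytoid marker Irf7 and the B cell marker Cd79b lay above 428 units at day 7, at 510 and 594.

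At day 7 against progenitor the metabolic and structural lists differed less, with medians of -0.33 for glycolysis, -0.38 for oxidative phosphorylation, -0.39 for cholesterol synthesis, -0.37 for ribosomal proteins, -0.51 for housekeeping genes, 0.25 for MHC class I and 0.08 for actin and adhesion, of which 12 of 47 members were higher and 5 lower. Within the last, Cd9, a tetraspanin gene, was 9.57-fold higher (log2 ratio 3.26, or 4.37 after quantile normalization) and Marcks at least 4.61-fold. At day 10 against day 7 that list had a median of 0.33, which turned to -0.20 after quantile normalization. With TNF oxidative phosphorylation, ribosomal protein and housekeeping genes had medians of -0.10 each. Of the 1949 probe sets without a gene symbol, controls left out, 111 were at least 2-fold higher and 102 lower at day 7, and 128 and 106 with TNF.

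Another pattern is that maturation genes stood high at day 7, before TNF; the test on T and NK cells was chosen after the result was seen and the overlap was fixed beforehand. T or NK cells in the culture, which express Ccl5 and Ccr7, are argued against: of 19 markers measured, 1 lay above 428 units and at least 2-fold above the progenitor array, where 5 or more were looked for. It may be that part of the TNF response was present at day 7 without added TNF, since 110 genes were higher in both comparisons, which share no array, 1.66 times the 66.1 that independent lists give. That met its prediction, but genes higher at day 7 and lower with TNF (1.51 times) and genes lower in both (1.70 times) were also in excess, a check added after the result was seen, and at the floor of 428 units the ratios were 2.63 for higher in both, 2.26 for higher at day 7 and lower with TNF and 1.32 for lower in both; lower at day 7 and higher with TNF was not in excess, at 0.88 and 0.89 times. The log2 ratios had a Spearman's rho of 0.06 across 6552 genes, which are not independent replicates, and of 32 maturation genes 14 were higher in both, against 11.3 for independent lists, so these data leave the hypothesis open.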
